A study of Homo sapiens with 18 samples.

How the data were processed

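RNA sequencing of 18 libraries from 2 human ovarian cancer cell lines was analysed, 9 libraries of A2780 and 9 of SKOV3. The labels place 3 libraries of each line in each of 3 groups: the DMSO solvent control, daphnetin at 20 mg/L and daphnetin at 40 mg/L. Libraries were prepared with a stranded mRNA kit, per the labels' protocols. Trimmomatic 0.36 and genome build GRCh38 are named in the submitters' processing notes. The deposited table holds whole-number read counts per gene for every library, not normalised, together with each gene's chromosome, start, end, strand and exonic length in bases. Its header has the layout of featureCounts output, per the file headers. The aligner, the counting program, the annotation release and the strand setting are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart, and the report gives the larger exon overlaps of named genes. The duration of treatment is not given either.

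The table listed 56303 genes, 35546 of them with a gene symbol. Total counts per library ran from 30016475 to 37220879 in A2780 and from 35105152 to 44132931 in SKOV3. Small counts were mostly even: 59913 values equalled 2 against 14622 equal to 1, and 74.3% to 77.0% of the counts from 1 to 12 in a library were even. Both mates of a read pair therefore appear to have been counted separately, and the totals overstate the number of fragments. 28 identifiers had been turned into dates, 2 of which occurred more than once. They held 0.161% to 0.194% of a library's counts and stayed in the totals, and no gene is named from them. Mitochondrial genes took 10.6% to 16.51% of the counts in A2780 libraries and 4.36% to 5.23% in SKOV3 libraries. Counts of replicate libraries differed by more than counting error in every pair, with a chi-square per degree of freedom from 5.03 to 34.69, so no pair looked like 1 library deposited more than once. This does not show that they are separate cultures. Sequencing depth sets counting error only, and reads without molecular identifiers are not independent molecules.

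Each line was fitted alone, because the lines have different expression profiles, and its 3 groups shared an estimate of the spread with 6 residual degrees of freedom. Genes were kept by edgeR's filterByExpr rule, which left 20593 genes in A2780 and 21936 in SKOV3. Library sizes were scaled by TMM. Differences were tested with edgeR 4.0.16 by the quasi-likelihood F test with robust dispersion estimates, in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, two-sided. The difference between the lines' responses at a dose was tested as an interaction contrast, SKOV3 minus A2780, in a fit of all 18 libraries with 23742 genes and 12 residual degrees of freedom. Expression levels are TMM-scaled counts relative to library size (CPM), given as mean ± SD of 3 libraries. They were scaled within a line, and over all 18 libraries where the lines are set side by side. Standard errors (SE) of log2 fold changes were taken from the F statistic. The common biological coefficient of variation was 7.7% in A2780 and 5.8% in SKOV3.

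A total of 30 gene lists with 660 entries was written from general knowledge: NRF2 targets, ferroptosis suppressors, ferroptosis drivers, iron homeostasis, integrated stress response, endoplasmic reticulum chaperones, heat shock response, metallothioneins and metal response, hypoxia response, aryl hydrocarbon receptor targets, p53 targets, mitotic genes, DNA replication genes, cholesterol synthesis, fatty acid synthesis and desaturation, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic ribosomal proteins, ribosome biogenesis, ERK pathway output, NF-kB and inflammatory genes, interferon response, TGF-beta and YAP output, epithelial genes, mesenchymal and invasion genes, lysosome and autophagy genes, replication-dependent histones, immune cell markers, and fibroblast and endothelial markers. Some genes stand in more than 1 list. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on log CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera asks whether a list ranks apart from all other genes. An estimated correlation and fry, which asks whether a list's genes move one way on balance, served as alternatives.

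The groups, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named NQO1, GPX4, SLC7A11, AIFM2, TFRC and HMOX1 in every comparison. It named the 6 genes of highest and the 6 of lowest fold change at 40 mg/L against DMSO, and 3 of each elsewhere. These had to have a symbol, be called, average at least 5 CPM in the higher group and, within a line, have no overlap between the libraries of both groups. Chance alone gives no overlap in 10% of genes with 3 libraries against 3. At 40 mg/L against DMSO the rule added the 2 members of smallest adjusted p of each called list and 1 of each other list. ERBB2 was added to check the labels. Results for some genes that these rules name are not reported here. Between the lines the rule named genes with a group at 0 counts, whose fitted fold depends on the prior count, and only their levels are given. A second choice, made after the values were seen, took the 3 highest and 3 lowest genes with at least 5 CPM in a group of each line. Members of lists that are named in the text outside these rules were also chosen after their values were seen.

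The alternatives chosen before the data were examined were the RLE size factors of DESeq2, a DESeq2 1.42.0 test, no filter on low counts, a filter of at least 1 CPM in 3 libraries, only the libraries of the groups compared, all 18 libraries in 1 fit, the replicate number as a block, each library left out in turn, and a log2 fold change of at least 1 in size. 2 alternatives were added after the data were seen: mitochondrial genes left out before scaling, and the pair of A2780 libraries with the lowest mitochondrial share left out. The closing section gives their effect. No column of the table lacked a sample, and no library was left out of the reported values. Overlaps of calls between doses were set beside 20 simulations of unchanged groups against the same DMSO libraries, and overlaps between lines were tested with Fisher's exact test across genes, one-sided. Genes are not independent replicates in that test.

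The scripts were tested on simulated data drawn from the real means and library sizes, with 200 changed genes. For A2780 at 40 mg/L, on 19973 genes, 76.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 12 false calls. For SKOV3 at 40 mg/L, on 21341 genes, the shares were 82.1%, 92.5% and 100%, with 12 false calls. A seeded shift of the mitotic list was recovered in both. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.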

Results

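Gene expression was measured by RNA sequencing in 2 human ovarian cancer cell lines, A2780 and SKOV3, after treatment with daphnetin, a dihydroxycoumarin found in plants, or with DMSO, its solvent. Each line had 3 groups of 3 libraries, DMSO, 20 mg/L daphnetin and 40 mg/L daphnetin, which gave 18 libraries. The series was designed to find transcripts and pathways that accompany the cell death and reduced movement caused by daphnetin, and its title names ferroptosis, an iron-dependent death by lipid peroxidation, and the quinone reductase NQO1. Total counts per library ranged from 30016475 to 37220879 in A2780 and from 35105152 to 44132931 in SKOV3. The labels number the replicates but do not say that they were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and gene lists with camera. Coordinates are those of build GRCh38.

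The labels of the lines were first checked with a gene known to differ between them. ERBB2, the receptor gene amplified in SKOV3 (chromosome 17, 39687914 to 39730426), averaged 64.6 ± 0.813 CPM in A2780 and 2760 ± 69 CPM in SKOV3 DMSO libraries (SD, n = 3). Within A2780, the first principal component held 37.3% of the variance and set the DMSO libraries (scores -43 to -40.6) apart from all treated ones (14.2 to 26.1). Within SKOV3 it held 54%, with DMSO libraries at -37.2 to -34.9, 20 mg/L at -22.7 to -20.8 and 40 mg/L at 54.5 to 62.9.

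To find the response of A2780 to the lower dose, 20 mg/L was compared with DMSO. HMOX1, which breaks down heme and releases iron (chromosome 22, 35380361 to 35394214), rose from 1.68 ± 0.36 to 25.5 ± 1.36 CPM, a 15-fold change (log2 3.91, SE 0.15, n = 3 per group, adjusted p = 7.21e-16). NQO1 (chromosome 16, 69706996 to 69726951) rose 2.18-fold, from 90.3 ± 4.11 to 196 ± 4.67 CPM (log2 1.12, SE 0.07, adjusted p = 2.25e-13), and 17.7% of its exonic bases overlap a gene on the opposite strand. SLC7A11, the cystine importer that feeds glutathione synthesis (chromosome 4, 138164097 to 138242349), rose 2.46-fold, from 7.91 ± 0.719 to 19.4 ± 1.22 CPM (log2 1.30, SE 0.10, adjusted p = 1.18e-11). OSGIN1, an oxidative stress response gene (chromosome 16, 83948282 to 83966332), rose 14.5-fold (log2 3.86, SE 0.20), and CYP1A1, a xenobiotic-metabolising monooxygenase (chromosome 15, 74719542 to 74725610), rose 5.04-fold (log2 2.33, SE 0.17). In each of these genes all 3 treated libraries lay above all 3 DMSO libraries.

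The strongest decreases were in HK2, a hexokinase of glycolysis (log2 -1.92, SE 0.11), DLG2, a scaffold protein gene (log2 -1.80, SE 0.13), and KIF20A, a kinesin of cell division (log2 -1.75, SE 0.08), with all 3 treated libraries below the DMSO libraries. Adjusted p values were 5.01e-12, 3.53e-12 and 1.78e-16. TFRC, the transferrin receptor (chromosome 3, 196027183 to 196082189), rose 1.21-fold, from 125 ± 10.2 to 151 ± 13.9 CPM (log2 0.28, SE 0.07, adjusted p = 0.00304), without overlap. GPX4, the peroxidase that reduces lipid peroxides (chromosome 19, 1103926 to 1106791), averaged 154 ± 16.2 CPM in DMSO and 131 ± 13.7 CPM at 20 mg/L, with overlapping libraries (log2 -0.23, SE 0.08, adjusted p = 0.0166). That call was lost without DMSO replicate 1 (adjusted p = 0.174), DMSO replicate 3 (0.0512) or 20 mg/L replicate 3 (0.131). AIFM2, which encodes the ferroptosis suppressor FSP1 (chromosome 10, 70098223 to 70132934), was not called (log2 0.31, SE 0.15, adjusted p = 0.108), but passed without DMSO replicate 2 (0.0492).

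Of 20593 genes tested in A2780 at 20 mg/L, 7602 (36.9%) were called, 3716 higher and 3886 lower, and 766 changed at least 2-fold. Of 26 targets of NRF2, the transcription factor of the oxidative stress response, 18 rose and the other 8 were not called (18 higher and 2 lower adjusted over the list alone, median log2 0.88, camera adjusted p = 4.29e-14). Among them TXNRD1, thioredoxin reductase, rose by log2 1.39 and GCLM, a subunit of the enzyme that starts glutathione synthesis, by log2 1.84. Of 30 p53 targets 25 rose (28 adjusted over the list alone, median log2 0.54, camera adjusted p = 3.5e-16), including CDKN1A, an inhibitor of cell cycle kinases, at log2 1.41 and MDM2, a ubiquitin ligase, at log2 0.94. Of 26 mitotic genes 25 fell and 1, NUSAP1, rose (the same numbers adjusted over the list alone, median log2 -0.73, camera adjusted p = 1.95e-19). Of 26 ribosome biogenesis genes 24 fell (24 adjusted over the list alone, median log2 -0.53, camera adjusted p = 3.15e-18). For these 4 lists the adjusted p = 0.134 with an estimated correlation.

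Further lists were called at 20 mg/L in A2780. Lysosome and autophagy genes were higher, 12 up and 2 down of 21 (14 and 2 adjusted over the list alone, median log2 0.32, camera adjusted p = 2.75e-05, and adjusted p = 0.149 with an estimated correlation). TGF-beta and YAP output was higher, 7 of 13 up (9 adjusted over the list alone, median log2 0.48, camera adjusted p = 0.000605, and adjusted p = 0.149 with an estimated correlation). Ferroptosis suppressors ranked higher with 9 up and 5 down of 25, the same numbers adjusted over the list alone (median log2 0.14, camera adjusted p = 0.0073, and adjusted p = 0.335 with an estimated correlation). The suppressors that fell were GPX4, DHODH, HSPB1, PDSS2 and VKORC1L1. Glycolysis genes were lower, 12 down and 1 up of 19 (13 and 1 adjusted over the list alone, median log2 -0.48, camera adjusted p = 2.17e-06, and adjusted p = 0.149 with an estimated correlation). Heat shock genes were lower, 11 down and 1 up of 17 (median log2 -0.36, camera adjusted p = 2.88e-05, and adjusted p = 0.247 with an estimated correlation).

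Of the 13 mitochondrially encoded genes 0 were called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2 (median log2 -0.23) at 20 mg/L in A2780. The list was not called (camera adjusted p = 0.0862) but passed without DMSO replicate 3 (0.0309), 20 mg/L replicate 1 (0.0321) or 20 mg/L replicate 3 (0.00814). Mitochondrial genes took 11.14% of the counts in 20 mg/L replicate 2, and without it and 40 mg/L replicate 1 (10.6%), the lowest shares of the line, 7082 genes were called. With an estimated correlation 0 of the 13 called lists passed, 7 of all lists at an unadjusted p under 0.05, while fry called 18.

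At 40 mg/L against DMSO in A2780, NQO1 reached 262 ± 23.6 CPM, 2.9-fold above DMSO (log2 1.54, SE 0.07, n = 3 per group, adjusted p = 1.86e-16), and SLC7A11 reached 26.3 ± 1.48 CPM, 3.33-fold above it (log2 1.74, SE 0.10, adjusted p = 2.22e-14). CYP1A1 had the highest fold change, from 1.21 ± 0.203 to 19.4 ± 1.73 CPM (15.9-fold, log2 3.99, SE 0.15, adjusted p = 7.25e-18). OSGIN1 rose 14.9-fold (log2 3.90, SE 0.20) and HMOX1 12.6-fold (log2 3.66, SE 0.15). MIR22HG, the host transcript of a microRNA, rose 5.48-fold, CYR61, a matrix protein induced by YAP, 4.96-fold, and PANX2, a pannexin channel gene, 4.72-fold. The lowest fold changes were in POTEC (log2 -2.28, SE 0.11), a member of a family of near-identical genes whose reads may be shared, PIF1, a helicase (-2.17, SE 0.10), KIF20A (-2.05, SE 0.08), HK2 (-1.98, SE 0.11), PLK1, a mitotic kinase (-1.97, SE 0.08), and GPC6, a glypican (-1.96, SE 0.16). All 3 treated libraries lay outside the range of the DMSO libraries in each of these genes.

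GPX4 averaged 139 ± 4.02 CPM at 40 mg/L in A2780 and was not called (log2 -0.15, SE 0.08, adjusted p = 0.115), though it passed without DMSO replicate 2 (0.0329). TFRC (log2 0.12, SE 0.07, adjusted p = 0.216) was not called either, and passed without DMSO replicate 1 (0.0443). AIFM2 had a log2 fold change of -0.08 (SE 0.15, adjusted p = 0.722). A total of 7595 genes (36.9%) were called, 3641 higher and 3954 lower, of which 884 changed at least 2-fold. Without the A2780 libraries of lowest mitochondrial share 7097 were called.

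NRF2 targets rose in 20 of 26 cases and 1, TRIM16, fell (log2 -0.51), with the same numbers adjusted over the list alone (median log2 1.04, camera adjusted p = 7.81e-18, and adjusted p = 0.0728 with an estimated correlation). TXNRD1 rose 3.11-fold, from 113 ± 4.6 to 350 ± 18.8 CPM (log2 1.64, SE 0.07, adjusted p = 7.57e-17). Ferroptosis suppressors rose in 10 of 25 cases and 2, DHODH and VKORC1L1, fell (median log2 0.14, camera adjusted p = 0.000152, and adjusted p = 0.136 with an estimated correlation). GCLM, named among the NRF2 targets at 20 mg/L, rose 3.83-fold (log2 1.94, SE 0.09). Of 27 ferroptosis drivers 10 rose and 3 fell (10 and 4 adjusted over the list alone, median log2 0.08, camera adjusted p = 0.0137, and adjusted p = 0.152 with an estimated correlation), among them SAT1, an enzyme of polyamine breakdown (log2 1.25, SE 0.09). Of 19 iron homeostasis genes 8 rose and 3 fell (median log2 0.06, camera adjusted p = 0.0891, which passed without DMSO replicate 1 at 0.0347). FTL, the ferritin light chain, rose 3.93-fold (log2 1.97, SE 0.10), and it has processed pseudogenes that could share its reads.

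Of 35 genes of the integrated stress response 20 rose and 4, CBS, DDIT4, SLC7A5 and PCK2, fell (20 and 6 adjusted over the list alone, median log2 0.34, camera adjusted p = 1.19e-05, and adjusted p = 0.0728 with an estimated correlation). DDIT3, the transcription factor CHOP, rose 2.3-fold (log2 1.20, SE 0.08), with 28% of its exonic bases overlapping MARS on the opposite strand. Endoplasmic reticulum chaperones ranked higher with 7 up and 3 down of 20 (8 and 4 adjusted over the list alone, median log2 0.16, camera adjusted p = 0.0169, and adjusted p = 0.386 with an estimated correlation). DNAJC3 (log2 0.81) and DNAJB9 (log2 1.05) rose, while HSP90B1, PDIA4 and CRELD2 fell. Heat shock genes fell in 9 of 17 cases and BAG3 rose (10 and 1 adjusted over the list alone, median log2 -0.27, camera adjusted p = 0.000652, and adjusted p = 0.229 with an estimated correlation), led by FKBP4 (log2 -0.77) and HSPE1 (log2 -0.64). Of 3 metallothionein and metal response genes, too few to test as a list, SLC30A1, a zinc exporter, rose (log2 0.73, SE 0.16).

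Of 30 p53 targets 27 rose (27 adjusted over the list alone, median log2 0.70, camera adjusted p = 3.33e-21, and adjusted p = 0.0728 with an estimated correlation). Called members included GADD45A, a growth arrest gene (log2 1.16, SE 0.08), and TP53INP1 (log2 1.02, SE 0.08). Of 26 mitotic genes 24 fell and NUSAP1 rose (the same adjusted over the list alone, median log2 -0.77, camera adjusted p = 3.33e-21, and adjusted p = 0.0728 with an estimated correlation). Of 26 ribosome biogenesis genes 23 fell (24 adjusted over the list alone, median log2 -0.54, camera adjusted p = 1.39e-15, and adjusted p = 0.0728 with an estimated correlation). DKC1 was at log2 -0.88 and NOLC1 at log2 -0.87. DNA replication genes were not called as a list (7 up, 10 down of 28, median log2 -0.03, mean 0, camera adjusted p = 0.988), while CCNE2, cyclin E2, with 37.1% of its exonic bases opposite INTS8, rose (log2 1.32, SE 0.11). MYC, a driver of cell growth, fell from 59.9 ± 4.58 to 28.8 ± 1.19 CPM (log2 -1.06, SE 0.07, adjusted p = 4.09e-12), within an ERK output list that was not called (5 up, 5 down of 18, median log2 -0.03, mean 0.17, camera adjusted p = 0.727).

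Metabolic lists were compared next in A2780 at 40 mg/L. Glycolysis genes fell in 13 of 19 cases and SLC2A3, a glucose transporter, rose (14 and 1 adjusted over the list alone, median log2 -0.38, camera adjusted p = 3.25e-07, and adjusted p = 0.101 with an estimated correlation). LDHA, lactate dehydrogenase, was at log2 -0.86. Hypoxia genes, which share HK2 and LDHA with that list, ranked lower with 13 down and 5 up of 28 (14 and 6 adjusted over the list alone, median log2 -0.29, camera adjusted p = 0.00926, and adjusted p = 0.327 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes ranked lower with 10 down and 1 up of 28 (median log2 -0.19, camera adjusted p = 0.00118, and adjusted p = 0.225 with an estimated correlation). Called members included NDUFB10 (log2 -0.75) and ATP5B (log2 -0.55). Cholesterol synthesis genes ranked higher with 9 up and 1 down of 23 (9 and 2 adjusted over the list alone, median log2 0.16, camera adjusted p = 0.0408, and adjusted p = 0.554 with an estimated correlation). Called members included STARD4 (log2 0.40) and SREBF2 (log2 0.33). That call was lost without DMSO replicate 2 (adjusted p = 0.0636) or 3 (0.118) and by fry (0.158). Fatty acid synthesis genes were not called as a list (7 down, 2 up of 16, median log2 -0.19, camera adjusted p = 0.0968), with ACACA, acetyl-CoA carboxylase, at log2 -0.63.

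Mitochondrially encoded genes ranked lower as a list at 40 mg/L in A2780 (median log2 -0.30, camera adjusted p = 0.0411, and adjusted p = 0.665 with an estimated correlation), though 0 of 13 were called by edgeR, 0 at an unadjusted p under 0.05 and 0 by DESeq2. MT-ND1 had log2 -0.48 (SE 0.25, adjusted p = 0.185) and MT-ND5 log2 -0.30 (SE 0.16, adjusted p = 0.195), and MT-ND1 passed without both A2780 libraries of lowest share (log2 -0.32, adjusted p = 0.0106). The list lost its call without DMSO replicate 2 (adjusted p = 0.15), without 40 mg/L replicate 1 (0.48), whose mitochondrial share of 10.6% was the lowest, without that pair (0.282) and by fry (0.324). Cytosolic ribosomal proteins were not called as a list (2 up, 3 down of 30, median log2 0, camera adjusted p = 0.881), with RPL35 at log2 -0.31.

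Signalling and lineage lists were also compared at 40 mg/L in A2780. TGF-beta and YAP output rose in 8 of 13 cases (8 adjusted over the list alone, median log2 0.92, camera adjusted p = 2.63e-05, and adjusted p = 0.0728 with an estimated correlation). Called members included SKIL (log2 1.39) and AMOTL2 (log2 1.26). Lysosome and autophagy genes rose in 16 of 21 cases (17 up and 1 down adjusted over the list alone, median log2 0.48, camera adjusted p = 6.42e-09, and adjusted p = 0.0728 with an estimated correlation). Called members included GABARAPL1 (log2 1.42, SE 0.09) and the autophagy receptor SQSTM1 (log2 1.05, SE 0.07). Aryl hydrocarbon receptor targets ranked higher with 4 up and 1 down of 9 (median log2 0.36, camera adjusted p = 0.0106, and adjusted p = 0.136 with an estimated correlation). NF-kB and inflammatory genes rose in 5 of 11 cases (median log2 0.35, camera adjusted p = 0.029, and adjusted p = 0.152 with an estimated correlation). Called members included TNFAIP3 (log2 1.31) and PTGS2 (log2 1.77), both under 4 CPM. Interferon response genes ranked higher with 8 up and 2 down of 16 (median log2 0.32, camera adjusted p = 0.0135, and adjusted p = 0.152 with an estimated correlation). OAS3 was at log2 0.85 and IFIT2 at log2 -1.04. Replication-dependent histones (3 up of 14, median log2 0.21, camera adjusted p = 0.0968), epithelial genes (1 down of 8, MUC1 at log2 -0.97, median -0.11, 0.625) and mesenchymal and invasion genes (2 up, 4 down of 17, TWIST1 at log2 -0.41, median -0.12, mean 0.03, 0.7) were not called.

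Markers of other cell types were compared last. Of 6 immune cell markers 1, CD14, was called, at 0.131 CPM against 0.439 CPM in DMSO (log2 -1.75, SE 0.61, adjusted p = 0.0209). It was lost without DMSO replicate 1 (adjusted p = 0.0901), 40 mg/L replicate 2 (0.114) or 40 mg/L replicate 3 (0.0768), and the list was not called (median log2 0.09, mean -0.1, camera adjusted p = 0.988). Fibroblast and endothelial markers ranked lower with 3 down of 8 (median log2 -0.25, camera adjusted p = 0.0408, and adjusted p = 0.252 with an estimated correlation). Called members included the collagen COL3A1 (log2 -0.89) and PDGFRA (log2 -0.66). That call was lost without DMSO replicate 3 (adjusted p = 0.0528), 40 mg/L replicate 1 (0.0517) or 40 mg/L replicate 2 (0.0681). Of the 20 lists called, 0 passed with an estimated correlation, 10 of all lists at an unadjusted p under 0.05, while fry called 21.

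**Figure D1:**
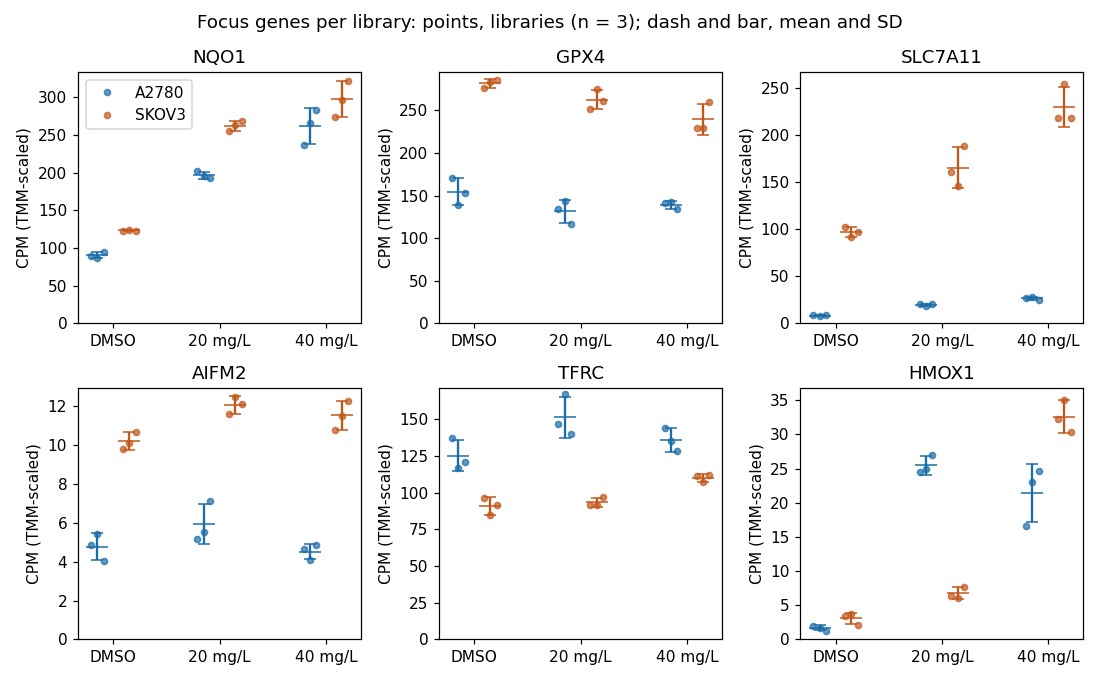
Expression of 6 genes of iron, cystine and lipid peroxide handling (CPM, vertical axis) by daphnetin dose (mg/L, horizontal axis) in A2780 and SKOV3, with a point per library, a dash at the mean of 3 libraries and a bar of 1 SD on each side. NQO1 rose from 90.3 to 262 CPM in A2780 and from 123 to 298 CPM in SKOV3, and HMOX1 from 1.68 to 21.4 CPM and from 3.07 to 32.6 CPM.

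The doses were then compared within A2780. From 20 to 40 mg/L NQO1 rose a further 1.33-fold (log2 0.41, SE 0.07, n = 3 per group, adjusted p = 0.000101) and SLC7A11 rose as well (log2 0.44, SE 0.09, adjusted p = 0.000963), both without overlap. HMOX1 did not pass (log2 -0.25, SE 0.11, adjusted p = 0.147), nor did GPX4 (log2 0.08, adjusted p = 0.553), TFRC (log2 -0.16, adjusted p = 0.143) or AIFM2 (log2 -0.39, adjusted p = 0.0782, but 0.0386 with all 18 libraries in 1 fit). CYP1A1 rose 3.16-fold from 6.14 ± 0.98 CPM (log2 1.66, SE 0.12), FBXL7, a ubiquitin ligase subunit, 2.51-fold (log2 1.33, SE 0.15) and CYR61 2.2-fold (log2 1.14, SE 0.19). The lowest were LCN12 (log2 -1.13, SE 0.16), NOSTRIN (-1.12, SE 0.15) and TPH1 (-1.11, SE 0.14), none with libraries overlapping between the doses. In all 2999 genes (14.6% of those tested) were called, 1382 higher and 1617 lower, with 173 changed at least 2-fold. The count was 1583 without 20 mg/L replicate 3, 1797 without 40 mg/L replicate 2 and 3126 without the pair of lowest mitochondrial share.

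Of 35 integrated stress response genes 19 were higher at 40 than at 20 mg/L in A2780 (23 adjusted over the list alone, median log2 0.30, camera adjusted p = 1.65e-11, and adjusted p = 0.0633 with an estimated correlation). NRF2 targets (10 up, 1 down of 26, median log2 0.19, camera adjusted p = 0.000233, and adjusted p = 0.49 with an estimated correlation), p53 targets (7 up, 1 down of 30, median log2 0.14, camera adjusted p = 0.00638, and adjusted p = 0.689 with an estimated correlation) and aryl hydrocarbon receptor targets (3 up of 9, median log2 0.21, camera adjusted p = 0.00443, and adjusted p = 0.335 with an estimated correlation) also ranked higher. Mitotic genes ranked lower (5 down of 26, median log2 -0.08, camera adjusted p = 0.0423, and adjusted p = 0.699 with an estimated correlation), a call lost without 20 mg/L replicate 1 (adjusted p = 0.535) or 2 (0.0707) and 40 mg/L replicate 1 (0.0764) or 3 (0.0614). By fry the NRF2 (0.0796), p53 (0.174) and mitotic (0.296) calls were lost, the last also with RLE size factors (0.0522) and without the pair of lowest mitochondrial share (0.11). Of 12 lists called between the doses, 0 passed with an estimated correlation, 2 of all lists at an unadjusted p under 0.05 and 2 by fry.

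In SKOV3 at 20 mg/L, compared with DMSO to find the response of this line to the lower dose, NQO1 rose 2.12-fold, from 123 ± 0.894 to 262 ± 6.73 CPM (log2 1.09, SE 0.05, n = 3 per group, adjusted p = 2.63e-16). HMOX1 rose 2.2-fold, from 3.07 ± 0.798 to 6.73 ± 0.875 CPM (log2 1.13, SE 0.13, adjusted p = 1.24e-07), and SLC7A11 1.71-fold, from 96.6 ± 5.21 to 165 ± 21.9 CPM (log2 0.77, SE 0.08, adjusted p = 3.58e-07). The highest fold changes were in ALDH3A1, an aldehyde dehydrogenase (3.63-fold, log2 1.86, SE 0.07), EGR1, an immediate early transcription factor (3.61-fold, log2 1.85, SE 0.17), and AKR1C2, an aldo-keto reductase with near-identical relatives (3.42-fold, log2 1.78, SE 0.06). The lowest were FILIP1L (log2 -1.39, SE 0.10), KIF20A (-1.27, SE 0.06) and WDR72 (-1.23, SE 0.17). All of these had no overlap between libraries of the groups. GPX4 (log2 -0.10, adjusted p = 0.27), AIFM2 (log2 0.24, adjusted p = 0.0769) and TFRC (log2 0.04, adjusted p = 0.756) were not called.

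Of 21936 genes tested in SKOV3 at 20 mg/L, 2217 (10.1%) were called, 1132 higher and 1085 lower, and 150 changed at least 2-fold. The count was 1443 without DMSO replicate 3 and 1466 with all 18 libraries in 1 fit. Of 30 NRF2 targets 28 rose (29 adjusted over the list alone, median log2 0.69, camera adjusted p = 6.75e-61, and adjusted p = 0.00653 with an estimated correlation). Of 35 integrated stress response genes 25 rose (28 adjusted over the list alone, median log2 0.35, camera adjusted p = 1.87e-30, and adjusted p = 0.00653 with an estimated correlation). Aryl hydrocarbon receptor targets rose in 9 of 11 cases and NEDD9 fell (median log2 1.08, camera adjusted p = 9.76e-18, and adjusted p = 0.0141 with an estimated correlation). All 26 mitotic genes fell (median log2 -0.62, camera adjusted p = 1.03e-54, and adjusted p = 0.0141 with an estimated correlation). Cholesterol synthesis genes fell in 19 of 24 cases and EBP and SC5D rose (median log2 -0.39, camera adjusted p = 5.76e-19, and adjusted p = 0.0141 with an estimated correlation). ERK output (9 up, 1 down of 19, median log2 0.16, camera adjusted p = 1.26e-09, and adjusted p = 0.0258 with an estimated correlation) and NF-kB genes (10 up, 1 down of 19, median log2 0.40, camera adjusted p = 6.45e-11, and adjusted p = 0.0365 with an estimated correlation) rose, including MYC at log2 0.64 and CXCL8 at log2 1.05.

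Of the 19 lists called in SKOV3 at 20 mg/L, 7 held and the others were lost with an estimated correlation. DNA replication genes rose in 22 of 28 cases (25 adjusted over the list alone, median log2 0.36, camera adjusted p = 8.51e-26, and adjusted p = 0.0666 with an estimated correlation). Called members included CDC6 and CCNE2. Heat shock genes fell in 12 of 18 cases (median log2 -0.18, camera adjusted p = 5.25e-11, and adjusted p = 0.0544 with an estimated correlation). Hypoxia genes (13 up, 3 down of 30, median log2 0.18, adjusted p = 0.0727 with an estimated correlation), ferroptosis suppressors (9 up, 3 down of 26, 0.23, adjusted p = 0.0888 with an estimated correlation), iron homeostasis genes (5 up of 20, 0.12, adjusted p = 0.0544 with an estimated correlation) and lysosome genes (6 up of 22, 0.14, adjusted p = 0.0727 with an estimated correlation) ranked higher. Fatty acid synthesis genes (8 down, 1 up of 16, median log2 -0.17, adjusted p = 0.0889 with an estimated correlation), histones (4 down of 14, -0.36, adjusted p = 0.0727 with an estimated correlation) and fibroblast and endothelial markers (4 down, 1 up of 11, -0.21, adjusted p = 0.0954 with an estimated correlation) ranked lower. Of 30 p53 targets 2, GDF15 (log2 1.88) and GADD45A (log2 0.59), rose and POLH fell, and the list was not called (median log2 0.01, camera adjusted p = 0.239).

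At 40 mg/L against DMSO in SKOV3, PIF1 fell from 22 ± 1.53 to 0.835 ± 0.123 CPM (log2 -4.71, SE 0.13, n = 3 per group, adjusted p = 5.4e-25), KIF20A from 193 ± 4.96 to 15.5 ± 0.699 CPM (log2 -3.63, SE 0.07, adjusted p = 8.25e-30), DLGAP5, a spindle protein gene, to log2 -3.54 (SE 0.07) and HMMR, a microtubule-binding hyaluronan receptor, to log2 -3.46 (SE 0.07). FAM72C (log2 -3.45, SE 0.17), which has near-identical paralogs, and HMMR-AS1 (log2 -3.43, SE 0.11), with 11.8% of its exonic bases opposite HMMR, completed the 6 lowest. ANGPT2, a vascular growth factor (chromosome 8, 6499651 to 6563409), rose 20.3-fold, from 5.15 ± 0.146 to 104 ± 13.3 CPM (log2 4.34, SE 0.15, adjusted p = 8.24e-11). OSGIN1 rose 16.9-fold, AKR1B10, an aldo-keto reductase, 15.3-fold, ATF3, a stress-induced transcription factor, 11.6-fold, HMOX1 10.7-fold to 32.6 ± 2.44 CPM (log2 3.42, SE 0.12, adjusted p = 6.14e-22) and GADD45A 8.71-fold. None of these genes had libraries that overlapped between the groups.

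NQO1 reached 298 ± 24 CPM in SKOV3 at 40 mg/L (2.41-fold, log2 1.27, SE 0.05, adjusted p = 9.79e-20) and SLC7A11 230 ± 21.2 CPM (2.38-fold, log2 1.25, SE 0.08, adjusted p = 1.36e-11). GPX4 fell from 282 ± 5.44 to 239 ± 17.7 CPM (log2 -0.24, SE 0.05, adjusted p = 0.000391) and TFRC rose from 90.8 ± 5.89 to 110 ± 2.26 CPM (log2 0.27, SE 0.05, adjusted p = 5.35e-05), each without overlap. AIFM2 was not called (log2 0.18, SE 0.09, adjusted p = 0.0943). In all 11425 genes (52.1%) were called, 5801 higher and 5624 lower, and 2271 changed at least 2-fold.

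Of 30 NRF2 targets 28 rose and CBR1, a carbonyl reductase, fell (median log2 1.24, camera adjusted p = 6.8e-24, and adjusted p = 0.0334 with an estimated correlation). SRXN1, sulfiredoxin, rose 7.29-fold (log2 2.87, SE 0.06), with 85% of its exonic bases shared with an overlapping gene on its strand, and TXNRD1 5.87-fold, from 230 ± 6.79 to 1350 ± 71 CPM (log2 2.55, SE 0.06). Ferroptosis suppressors ranked higher with 12 up and 7 down of 26 (13 and 7 adjusted over the list alone, median log2 0.15, camera adjusted p = 0.0317, and adjusted p = 0.44 with an estimated correlation). GCLC, the catalytic subunit for glutathione synthesis, rose 4.2-fold and FTL 3.79-fold, while SCD, HSPB1, PROM2, DHCR7, MBOAT1, MBOAT2 and GPX4 fell. Ferroptosis drivers went both ways (9 up, 10 down of 27, median log2 -0.10, mean 0.15, camera adjusted p = 0.954), as did iron homeostasis genes (8 up, 6 down of 20, median log2 0.07, camera adjusted p = 0.278). Of 4 metallothionein and metal response genes, too few to test, MTF1 rose (log2 0.50), while MT1X (log2 -2.34) and MT2A (log2 -1.41) fell.

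Of 35 integrated stress response genes 28 rose and 4, DDIT4, VLDLR, PSPH and CBS, fell (30 and 4 adjusted over the list alone, median log2 0.72, camera adjusted p = 1.78e-15, and adjusted p = 0.0284 with an estimated correlation). ATF3 (log2 3.53, SE 0.09) and DDIT3 (log2 1.99, SE 0.05) led them. Endoplasmic reticulum chaperones rose in 19 of 20 cases (19 adjusted over the list alone, median log2 0.68, camera adjusted p = 2.13e-15, and adjusted p = 0.0763 with an estimated correlation). HSPA5, the main chaperone of that compartment, rose 3.42-fold, from 647 ± 53.8 to 2210 ± 98.4 CPM (log2 1.77, SE 0.06, adjusted p = 3.98e-23), and DNAJB9 3.7-fold. Heat shock genes ranked lower with 9 down and 2 up of 18 (median log2 -0.13, camera adjusted p = 0.00895, and adjusted p = 0.368 with an estimated correlation). Called members included HSPB1 (log2 -1.51) and HSPH1 (log2 -0.52).

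All 26 mitotic genes fell in SKOV3 at 40 mg/L (26 adjusted over the list alone, median log2 -2.10, camera adjusted p = 2.97e-36, and adjusted p = 0.0334 with an estimated correlation). Called members included CCNB1, cyclin B1 (log2 -3.08, SE 0.06). DNA replication genes rose in 16 of 28 cases and 4 fell (median log2 0.33, camera adjusted p = 0.000864, and adjusted p = 0.477 with an estimated correlation). CDC6, a replication licensing factor, was at log2 1.16 and CCNE2 at log2 1.48. Of 30 p53 targets 16 rose and 4, FAS, DDB2, PHLDA3 and POLH, fell (16 and 5 adjusted over the list alone, median log2 0.17, camera adjusted p = 0.00668, and adjusted p = 0.0668 with an estimated correlation). GADD45A was at log2 3.12 and PLK2 at log2 0.77. MYC rose 3.23-fold, from 20 ± 0.224 to 64.6 ± 3.88 CPM (log2 1.69, SE 0.06, adjusted p = 7.27e-22), in an ERK output list that went both ways (7 up, 7 down of 19, median log2 -0.02, mean 0.25, camera adjusted p = 0.538). Ribosome biogenesis genes ranked higher with 15 up and 4 down of 26 (median log2 0.19, camera adjusted p = 0.0017, and adjusted p = 0.368 with an estimated correlation). Called members included GNL3 (log2 0.52) and PPAN (log2 0.87), which shares 59.8% of its exonic bases with a read-through gene. Cytosolic ribosomal proteins rose in 21 of 30 cases and RPL35 fell (median log2 0.20, camera adjusted p = 0.000343, and adjusted p = 0.508 with an estimated correlation), with RPS27 at log2 0.43.

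Cholesterol synthesis genes fell in 21 of 24 cases and EBP rose (median log2 -0.80, camera adjusted p = 5.95e-12, and adjusted p = 0.0334 with an estimated correlation). HMGCS1 (log2 -1.39) and FDFT1 (log2 -1.5) were among them. Fatty acid synthesis genes fell in 11 of 16 cases and ACSL1 rose (median log2 -0.60, camera adjusted p = 6.76e-07, and adjusted p = 0.0895 with an estimated correlation). SCD, the stearoyl-CoA desaturase, was at log2 -1.81 and ACACA at log2 -0.87. Glycolysis genes ranked lower with 11 down and 3 up of 19 (median log2 -0.24, camera adjusted p = 0.0234, and adjusted p = 0.496 with an estimated correlation), a call lost without 40 mg/L replicate 1 (0.0641), including SLC16A3 (log2 -0.58) and SLC2A1 (log2 -0.52). Hypoxia genes went both ways (12 up, 13 down of 30, median log2 -0.08, camera adjusted p = 0.973), with STC1 at log2 -1.13. Nuclear-encoded oxidative phosphorylation genes were not called as a list (14 down, 1 up of 28, median log2 -0.11, camera adjusted p = 0.0578), with COX5B at log2 -0.43. The list passed without DMSO replicate 1 (0.0239) or 40 mg/L replicate 3 (0.0169). Of 13 mitochondrially encoded genes 12 fell and MT-CO1 rose (median log2 -0.76, camera adjusted p = 2.4e-07, and adjusted p = 0.208 with an estimated correlation). MT-CO3 was at log2 -0.92. In the same libraries MT-RNR2, the large mitochondrial ribosomal RNA, took 1.99% to 2.11% of all counts, against 0.77% to 0.87% in DMSO.

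Interferon response genes fell in 19 of 22 cases and STAT2 and IRF7 rose (median log2 -0.74, camera adjusted p = 7.32e-07, and adjusted p = 0.0334 with an estimated correlation). MX1 was at log2 -1.25 and IFIT1 at log2 -1.46. Epithelial genes fell in 11 of 15 cases and OCLN rose (median log2 -0.81, camera adjusted p = 3.6e-06, and adjusted p = 0.0284 with an estimated correlation). The keratin KRT19 was at log2 -1.96 and KRT7 at log2 -1.17. Mesenchymal and invasion genes fell in 13 of 20 cases and SNAI2, MMP14 and CD44 rose (median log2 -0.38, camera adjusted p = 0.00255, and adjusted p = 0.214 with an estimated correlation). MMP1, a collagenase, fell from 899 ± 26.9 to 358 ± 27 CPM (log2 -1.33, SE 0.06), and ITGB3, with 51.6% of its exonic bases in an overlapping gene on its strand, had log2 -0.89. Fibroblast and endothelial markers fell in 10 of 11 cases and KDR rose (median log2 -1.10, camera adjusted p = 4.8e-05, and adjusted p = 0.0763 with an estimated correlation). COL1A2 was at log2 -0.93 and COL3A1 at log2 -2.03.

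TGF-beta and YAP output ranked higher in SKOV3 at 40 mg/L with 8 up and 5 down of 14 (median log2 0.34, camera adjusted p = 0.027, and adjusted p = 0.465 with an estimated correlation). Called members included CTGF (log2 2.25) and CYR61 (log2 1.96). Lysosome and autophagy genes rose in 14 of 22 cases and 2, TFEB among them, fell (16 and 2 adjusted over the list alone, median log2 0.23, camera adjusted p = 0.000124, and adjusted p = 0.0844 with an estimated correlation). SQSTM1 was at log2 1.71, 22% of whose exonic bases lie opposite another gene, and GABARAPL1 at log2 0.86. Aryl hydrocarbon receptor targets ranked higher with 7 up and 4 down of 11 (median log2 0.68, camera adjusted p = 0.0227, and adjusted p = 0.368 with an estimated correlation). Here TIPARP rose (log2 0.89), while ALDH3A1, highest at 20 mg/L, fell below DMSO (log2 -0.28, SE 0.07). NF-kB genes went both ways (7 up, 5 down of 19, median log2 -0.17, mean 0.15, camera adjusted p = 0.592), with CXCL8 at log2 1.33. Histones (4 down of 14, median log2 -0.42, camera adjusted p = 0.153) included HIST1H2BH at log2 -2.24, under 2 CPM. Of 3 immune cell markers, too few to test, CD68 rose (log2 0.38).

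**Figure D2:**
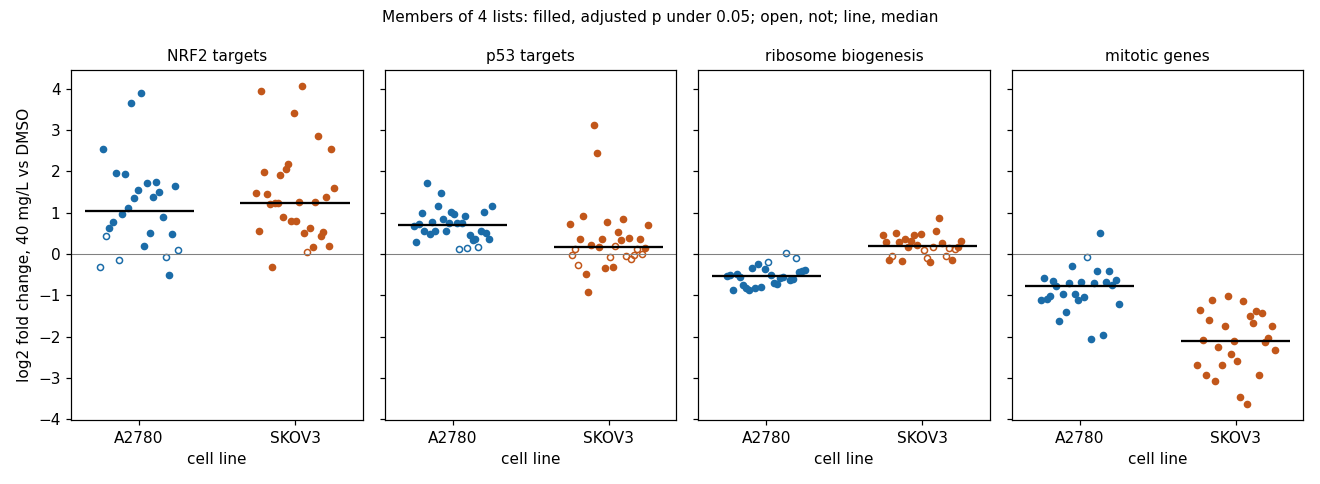
Log2 fold change at 40 mg/L against DMSO (vertical axis) of each tested member of 4 gene lists in A2780 and SKOV3 (horizontal axis). Each gene is a point, filled where the adjusted p is under 0.05, with a line at the list's median. The medians were 1.04 and 1.24 for NRF2 targets, 0.70 and 0.17 for p53 targets, -0.54 and 0.19 for ribosome biogenesis and -0.77 and -2.10 for mitotic genes.

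The doses were compared within SKOV3 in the same way. From 20 to 40 mg/L HMOX1 rose 4.86-fold (log2 2.28, SE 0.11, n = 3 per group, adjusted p = 3.28e-18), SLC7A11 rose by log2 0.48 (SE 0.08, adjusted p = 2.4e-05), TFRC by log2 0.24 (SE 0.05, adjusted p = 0.000401) and NQO1 1.13-fold (log2 0.18, SE 0.05, adjusted p = 0.00508), each without overlap. GPX4 was lower at the higher dose (log2 -0.13, SE 0.05, adjusted p = 0.0396), with overlapping libraries. That call was lost in 3 alternative fits (adjusted p 0.0585 to 0.0967) and without 20 mg/L replicate 2 (0.182) or 3 (0.0722) or 40 mg/L replicate 1 (0.187) or 2 (0.171). AIFM2 was not called (log2 -0.07, adjusted p = 0.558). KIAA1683 (8.64-fold, log2 3.11, SE 0.19), OSGIN1 (7.93-fold, log2 2.99, SE 0.13) and ATF3 (6.68-fold, log2 2.74, SE 0.09) had the highest fold changes. PIF1 (log2 -3.68, SE 0.14), MEFV, the pyrin gene (-3.55, SE 0.14), and CYP24A1, which breaks down vitamin D (-3.53, SE 0.18), had the lowest, all without overlap. A total of 10394 genes (47.4%) were called, 5081 higher and 5313 lower, with 1749 changed at least 2-fold.

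Between the doses in SKOV3, 17 lists were called. Epithelial genes (11 down, 1 up of 15, median log2 -0.75, camera adjusted p = 8.33e-07) alone held with an estimated correlation (0.0395). Mitotic genes fell further, all 26 of them (median log2 -1.41, camera adjusted p = 6.83e-34, and adjusted p = 0.0554 with an estimated correlation), as did interferon genes (17 down, 1 up of 22, median log2 -0.51, camera adjusted p = 1.23e-06, and adjusted p = 0.0554 with an estimated correlation). Endoplasmic reticulum chaperones rose in 19 of 20 cases (median log2 0.72, camera adjusted p = 3.85e-18, and adjusted p = 0.0744 with an estimated correlation). Integrated stress response genes (25 up, 5 down of 35, median log2 0.46, adjusted p = 0.0554 with an estimated correlation), NRF2 targets (21 up, 4 down of 30, 0.37, adjusted p = 0.164 with an estimated correlation) and p53 targets (16 up, 3 down of 30, 0.24, adjusted p = 0.0744 with an estimated correlation) ranked higher. So did lysosome genes (12 up, 3 down of 22, median log2 0.20, adjusted p = 0.182 with an estimated correlation) and ribosome biogenesis (16 up, 2 down of 26, 0.17, adjusted p = 0.344 with an estimated correlation).

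**Figure D3:**
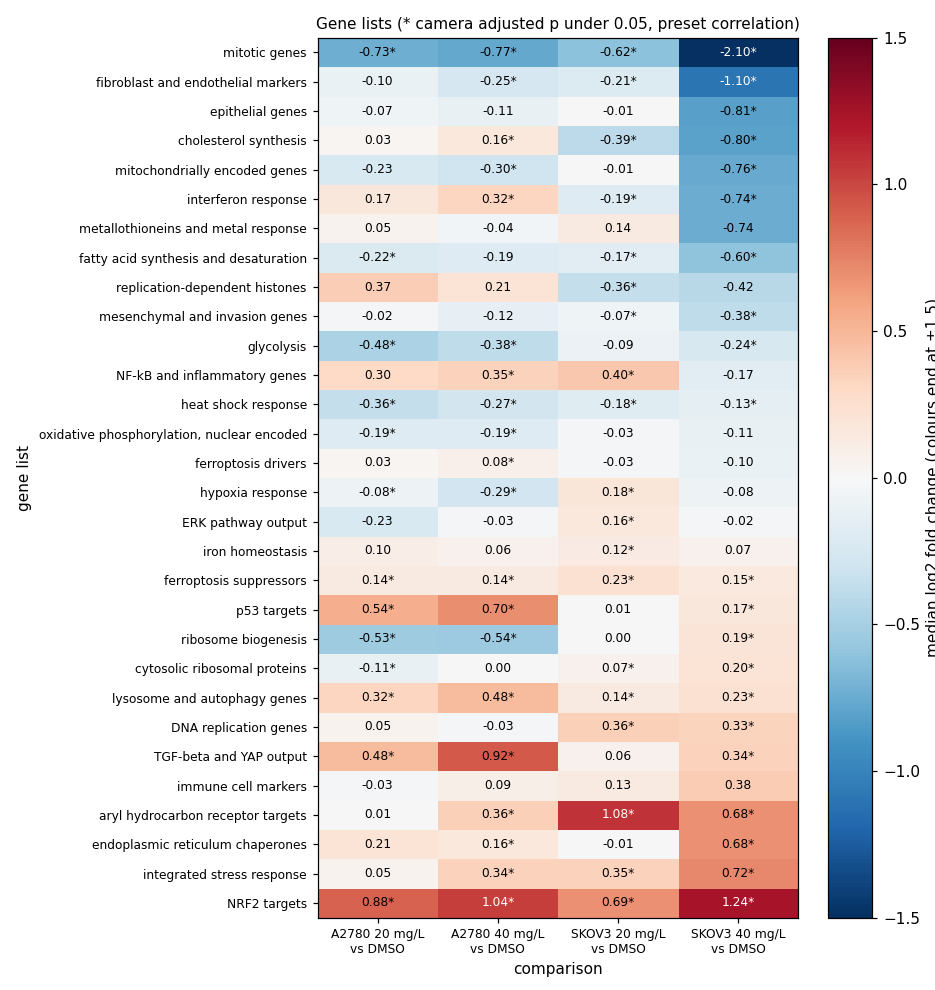
Median log2 fold change against DMSO (colour, ending at 1.5 on either side of 0) of 30 gene lists (vertical axis) in 4 comparisons, 20 and 40 mg/L in A2780 and SKOV3 (horizontal axis), with an asterisk where the camera adjusted p is under 0.05. Ribosome biogenesis was lower in A2780 (-0.53 and -0.54) and near 0 or higher in SKOV3 (0 and 0.19), while mitotic genes were lower in all 4 comparisons (-0.73, -0.77, -0.62 and -2.10).

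Whether the lines responded differently was tested as the SKOV3 response minus the A2780 response. At 20 mg/L HMOX1 responded less in SKOV3 (difference log2 -2.78, SE 0.24, n = 3 per group, adjusted p = 9.82e-10) and so did SLC7A11 (-0.53, SE 0.12, adjusted p = 0.00106). NQO1 (-0.04, SE 0.09, adjusted p = 0.824), GPX4 (0.12, adjusted p = 0.415) and AIFM2 (-0.07, adjusted p = 0.842) did not pass. TFRC (-0.25, SE 0.09, adjusted p = 0.0541) did not pass but did so in several alternatives, the lowest adjusted p being 0.0151 without A2780 20 mg/L replicate 3. Among genes at 5 CPM or more in both lines, HK2 had the highest difference (2.39, SE 0.14), since it fell in A2780 from 48.4 ± 7.13 to 12.9 ± 2.14 CPM and was 35.1 ± 1.11 and 49.1 ± 3.81 CPM in SKOV3. SLC7A5, an amino acid transporter (2.03, SE 0.15), and MT-TF, a mitochondrial tRNA (1.85, SE 0.22), followed. The lowest were HMOX1, MIR22HG (-2.32, SE 0.14) and DNAJB4, a cochaperone (-2.04, SE 0.12). In all 5121 of 23742 genes (21.6%) differed, 2616 with a higher and 2505 with a lower response in SKOV3, 791 at least 2-fold. Without the A2780 libraries of lowest mitochondrial share there were 4870.

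By the rule for named genes the extremes at 20 mg/L were genes with a group of A2780 libraries at 0 counts, for which no fold is given. KRT19 was at 165 ± 5.93 CPM in SKOV3 DMSO and 100 ± 12.3 CPM at 20 mg/L, against 0.246 and 0 CPM in A2780. UGT1A9 and UGT1A5 have exons that overlap UGT1A8 and may share its reads. These genes were at 24.5 and 24 CPM in SKOV3 DMSO and 55 and 53.2 CPM at 20 mg/L, against 0.0609 CPM for each in A2780 DMSO and 0 CPM with treatment. SDPR, SGCE and HOXA13 were at 77.3, 34.6 and 11.3 CPM in SKOV3 DMSO and 48.7, 36.2 and 9.16 CPM at 20 mg/L, against 0 CPM in A2780 DMSO and 0.0784, 0.106 and 0.0746 CPM with treatment.

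Ribosome biogenesis genes had a higher response in SKOV3 than in A2780 at 20 mg/L in 23 of 26 cases (24 adjusted over the list alone, median difference 0.58, camera adjusted p = 7.34e-21, and adjusted p = 0.0305 with an estimated correlation). Of 30 p53 targets 19 responded less and 1 more in SKOV3 (22 and 1 adjusted over the list alone, median difference -0.42, camera adjusted p = 1.41e-11, and adjusted p = 0.0563 with an estimated correlation). Cholesterol synthesis genes had a lower response in 15 of 24 cases and a higher one in 1 (median difference -0.48, or -0.49 without a gene with a group at 0 counts, camera adjusted p = 3.65e-08, and adjusted p = 0.133 with an estimated correlation). Histones (6 lower of 14, median difference -1, adjusted p = 0.0904 with an estimated correlation), TGF-beta and YAP output (7 lower of 14, -0.52, or -0.43 without such a gene, adjusted p = 0.149 with an estimated correlation), interferon genes (7 lower, 1 higher of 22, -0.40, adjusted p = 0.163 with an estimated correlation) and lysosome genes (5 lower, 1 higher of 22, -0.16, adjusted p = 0.278 with an estimated correlation) were lower in SKOV3.

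The lists higher in SKOV3 at 20 mg/L were the integrated stress response (14 higher, 4 lower of 35, median difference 0.24, adjusted p = 0.0904 with an estimated correlation), DNA replication (16 and 1 of 28, 0.31, adjusted p = 0.411 with an estimated correlation), hypoxia (12 and 3 of 30, 0.21, adjusted p = 0.149 with an estimated correlation), glycolysis (9 and 1 of 19, 0.26, adjusted p = 0.197 with an estimated correlation) and aryl hydrocarbon receptor targets (6 of 11, 0.64, adjusted p = 0.163 with an estimated correlation). ERK output (10 and 3 of 19, 0.54, adjusted p = 0.229 with an estimated correlation) and cytosolic ribosomal proteins (8 of 30, 0.20, adjusted p = 0.517 with an estimated correlation) were higher as well. Oxidative phosphorylation (6 and 1 of 28, 0.14, camera adjusted p = 0.0195, and adjusted p = 0.517 with an estimated correlation) was lost by fry (0.0552) and without SKOV3 DMSO replicate 1 (0.0552) or 20 mg/L replicate 2 (0.0594). Mitotic genes (9 and 1 of 26, 0.13, camera adjusted p = 0.0195, and adjusted p = 0.558 with an estimated correlation) were lost by fry (0.14) and without A2780 20 mg/L replicate 3 (0.151), SKOV3 DMSO replicate 2 (0.0532) or SKOV3 20 mg/L replicate 1 (0.0524). NRF2 targets were not called (10 and 13 of 30, -0.02, camera adjusted p = 0.356).

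At 40 mg/L NQO1 responded less in SKOV3 than in A2780 (difference log2 -0.29, SE 0.09, n = 3 per group, adjusted p = 0.0115), a call lost without A2780 40 mg/L replicate 3 (-0.23, adjusted p = 0.0666), and SLC7A11 responded less too (-0.51, SE 0.12, adjusted p = 0.000897). HMOX1 (-0.27, adjusted p = 0.452), GPX4 (-0.11, adjusted p = 0.459), AIFM2 (0.23, adjusted p = 0.332) and TFRC (0.13, adjusted p = 0.304) did not pass. MYC moved in opposite directions, from 58.8 ± 4.49 to 28.7 ± 1.07 CPM in A2780 and from 20.2 ± 0.249 to 65.1 ± 4.01 CPM in SKOV3 (difference 2.72, SE 0.10, adjusted p = 1.23e-23). Among genes at 5 CPM or more in both lines, TRIM16L, a pseudogene close in sequence to TRIM16 (2.81, SE 0.16), MYC and SLC7A5 (2.54, SE 0.15) had the highest differences. DLGAP5 (-2.63, SE 0.10), PIF1 (-2.56, SE 0.19) and HMMR (-2.45, SE 0.11) had the lowest. In all 7102 genes (29.9%) differed, 3386 higher and 3716 lower in SKOV3, 1721 at least 2-fold. The balance was less even with RLE size factors (2985 higher and 4154 lower) and by DESeq2 (3094 and 4334). Without the A2780 libraries of lowest mitochondrial share 6937 differed.

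The rule again named genes at 0 counts in a group of A2780 libraries. TMEM132B and FAM83G were at 3.47 and 7.19 CPM in SKOV3 DMSO and 9.45 and 11.1 CPM at 40 mg/L, against 0.0597 and 0.0589 CPM in A2780 DMSO and 0 CPM with treatment. SORBS2, CDH11 and KRT5 were at 14.4, 13.8 and 15.1 CPM in SKOV3 DMSO and 3.43, 6.71 and 4.69 CPM at 40 mg/L, against 0 CPM in A2780 DMSO and 0.0421, 0.075 and 0.0421 CPM with treatment.

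All 26 mitotic genes fell more in SKOV3 than in A2780 at 40 mg/L (26 adjusted over the list alone, median difference -1.20, camera adjusted p = 1.01e-30, and adjusted p = 0.0204 with an estimated correlation). Ribosome biogenesis genes had a higher response in SKOV3 in 25 of 26 cases (median difference 0.70, camera adjusted p = 4.94e-20, and adjusted p = 0.0188 with an estimated correlation). Cholesterol synthesis genes had a lower one in 20 of 24 cases and a higher one in 1 (21 and 1 adjusted over the list alone, median difference -0.82, or -0.83 without a gene with a group at 0 counts, camera adjusted p = 2.89e-15, and adjusted p = 0.0204 with an estimated correlation). Interferon genes (13 lower, 1 higher of 22, median difference -1.12, camera adjusted p = 1.39e-06, and adjusted p = 0.0188 with an estimated correlation) and the integrated stress response (23 higher, 7 lower of 35, 0.45, camera adjusted p = 7.79e-07, and adjusted p = 0.0204 with an estimated correlation) also held with an estimated correlation. Endoplasmic reticulum chaperones had a higher response in SKOV3 in 15 of 20 cases (0.46, camera adjusted p = 1.39e-10, and adjusted p = 0.058 with an estimated correlation). Of 30 p53 targets 18 responded less and 3 more in SKOV3 (22 and 3 adjusted over the list alone, median difference -0.48, camera adjusted p = 1.14e-05, and adjusted p = 0.135 with an estimated correlation).

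The remaining lists that differed at 40 mg/L were higher in SKOV3 for hypoxia (12 higher, 4 lower of 30, median difference 0.24, adjusted p = 0.288 with an estimated correlation), DNA replication (14 and 3 of 28, 0.32, adjusted p = 0.533 with an estimated correlation), glycolysis (10 and 1 of 19, 0.35, adjusted p = 0.288 with an estimated correlation) and cytosolic ribosomal proteins (9 of 30, 0.18, adjusted p = 0.572 with an estimated correlation). NRF2 targets (13 and 9 of 30, 0.37, camera adjusted p = 0.0197, and adjusted p = 0.371 with an estimated correlation) were lost without SKOV3 40 mg/L replicate 3 (0.0523). Lower in SKOV3 were fatty acid synthesis (9 of 16, median difference -0.28, adjusted p = 0.163 with an estimated correlation), histones (7 of 14, -0.65, adjusted p = 0.136 with an estimated correlation) and fibroblast and endothelial markers (7 of 11, -0.81, or -0.99 without a gene with a group at 0 counts, adjusted p = 0.113 with an estimated correlation). The growth protocol names 2 media with different serum, which may differ between the lines, so line and medium may not be separable here.

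The sharing of calls was counted last. In A2780, 5060 genes were called at both doses in the same direction, 2413 higher and 2647 lower, where independent lists would share 657 and 746, and 53 were called in opposite directions. In SKOV3 the count was 1638, 724 higher and 914 lower, where independent lists would share 299 and 278, with 191 in opposite directions. Both doses shared the DMSO libraries. In 20 simulations of unchanged groups at most 4 genes were called at a dose and 1 shared, too few to judge sharing. The covariance of the log2 fold changes of the doses across genes was 0.18 in A2780 against 0.0251 simulated, and 0.107 in SKOV3 against 0.0228, while the correlations were 0.73 and 0.47 against 0.51 and 0.50 simulated. The 3 controls could not be split into pairs, so some sharing may come from them. Between the lines, of 18806 genes tested in both, 740 were called in the same direction at 20 mg/L (331 higher and 409 lower, where independent lists would share 184 and 191, Fisher's exact p = 5.16e-31 and 1.45e-61) and 276 in opposite directions. At 40 mg/L 3444 genes were called in the same direction (1834 higher and 1610 lower, against 1013 and 926, Fisher's exact p = 5.38e-233 and 2.56e-169) and 1176 in opposite directions.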

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

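Each value here is a difference between the lines, the SKOV3 response minus the A2780 response in log2, that passed its main test (for lists, camera with a preset correlation), and the 3-against-3 and between-line splits and the test of low expression were chosen before the result was seen, while the comparison of p53 targets with NRF2 targets was chosen after it. It covers the lists called between the lines and the genes named in both lines at that dose or between the lines, except genes with a group at 0 counts. With an estimated correlation 1 of the 16 lists at 20 mg/L, ribosome biogenesis, kept its call, and 5 of the 15 at 40 mg/L, which were mitotic genes, ribosome biogenesis, cholesterol synthesis, interferon genes and the integrated stress response.

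At 20 mg/L the median difference was 0.24 for the integrated stress response, 0.21 for hypoxia, 0.64 for aryl hydrocarbon receptor targets, 0.13 for mitotic genes, 0.31 for DNA replication, 0.26 for glycolysis, 0.14 for oxidative phosphorylation, 0.2 for cytosolic ribosomal proteins, 0.58 for ribosome biogenesis and 0.54 for ERK output. It was -0.42 for p53 targets, -0.48 for cholesterol synthesis, -0.4 for interferon genes, -0.52 for TGF-beta and YAP output, -0.16 for lysosome genes and -1 for histones. Among genes it was -0.53 for SLC7A11, -2.78 for HMOX1, 0.48 for KIF20A, 2.39 for HK2, 2.03 for SLC7A5, 1.85 for MT-TF, -2.32 for MIR22HG and -2.04 for DNAJB4. The call of oxidative phosphorylation was lost with an estimated correlation (adjusted p = 0.517), by fry (0.0552) and without SKOV3 DMSO replicate 1 (0.0552) or SKOV3 20 mg/L replicate 2 (0.0594). Mitotic genes were lost with an estimated correlation (0.558), by fry (0.14) and without A2780 20 mg/L replicate 3 (0.151), SKOV3 DMSO replicate 2 (0.0532) or SKOV3 20 mg/L replicate 1 (0.0524), and cytosolic ribosomal proteins by fry (0.0795 here and 0.0947 at 40 mg/L).

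At 40 mg/L the median difference was 0.37 for NRF2 targets, 0.45 for the integrated stress response, 0.46 for endoplasmic reticulum chaperones, 0.24 for hypoxia, 0.32 for DNA replication, 0.35 for glycolysis, 0.18 for cytosolic ribosomal proteins and 0.7 for ribosome biogenesis. It was -0.48 for p53 targets, -1.2 for mitotic genes, -0.82 for cholesterol synthesis, -0.28 for fatty acid synthesis, -1.12 for interferon genes, -0.65 for histones and -0.81 for fibroblast and endothelial markers. Among genes it was 0.89 for TXNRD1, 0.76 for DDIT3, 0.82 for DNAJB9, 1.94 for GADD45A, 2.72 for MYC, 0.63 for SQSTM1, 2.81 for TRIM16L and 2.54 for SLC7A5. It was -0.29 for NQO1, -0.51 for SLC7A11, -2.56 for PIF1, -1.61 for KIF20A, -0.27 for ACACA, -0.58 for GABARAPL1, -1.16 for COL3A1, -2.63 for DLGAP5 and -2.45 for HMMR.

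Targets of p53 had a lower median response in SKOV3 than in A2780 at both doses, a call of camera lost with an estimated correlation (adjusted p = 0.0563 at 20 mg/L and 0.135 at 40 mg/L). Low expression in SKOV3 is argued against: over the 23 targets with at least 5 CPM in DMSO of both lines the median difference was -0.53 (SE 0.10) at 20 mg/L and -0.49 (SE 0.12) at 40 mg/L. A generally smaller response of SKOV3 is argued against at 40 mg/L, where the median difference of p53 less NRF2 targets was -0.85 (SE 0.25). It stays open at 20 mg/L (-0.4, SE 0.28). These SEs treat genes as independent and measure no spread between libraries. A pathway difference was not tested, and medium and line may be confounded.

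Within a line, 3 libraries against 3 make 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many called genes in each comparison. In A2780 the real count was 7602 at 20 mg/L, 7595 at 40 mg/L and 2999 between the doses. In SKOV3 it was 2217, 11425 and 10394. The highest count of any other split by edgeR was 0 in all 6, where at an unadjusted p under 0.05 the real counts were 9221, 9218, 5778, 4782, 12466 and 11626 and the highest others 912, 630, 1363, 1098, 735 and 754 (DESeq2 was not run on the splits). For gene lists at 20 and 40 mg/L, real and highest other counts were 13 and 12, then 20 and 14 in A2780, and 19 and 14, then 21 and 14 in SKOV3, with 1 of 10 splits as large in each.

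For the differences between the lines 30 splits were drawn. For genes 1 of 30, the real one, gave as many at 20 mg/L (5121, highest other 4556) and at 40 mg/L (7102, highest other 4941). That is the smallest share that 30 splits can give, and the other splits mix treated and DMSO libraries. Chance is therefore not excluded by these gene counts or by the number of lists called. That number was reached by 5 of 30 splits at 20 mg/L (16, highest other 20) and 9 of 30 at 40 mg/L (15, highest other 20). By construction another split can hold the treatment contrast of a single line, which may account for its calls.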

How the results depend on the processing

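Leaving out mitochondrial genes and leaving out the A2780 libraries of lowest mitochondrial share were chosen after the results were seen, and all other alternatives before. Of 294 values of 18 counts under the alternatives, 276 stayed within 1.5 times the reported count. With a log2 fold change of at least 1 required, which by construction lowers counts, 766, 884 and 173 genes were left in A2780 (20 mg/L, 40 mg/L, between doses), 150, 2271 and 1749 in SKOV3, and 791 and 1721 between the lines at 20 and 40 mg/L. With all 18 libraries in 1 fit SKOV3 at 20 mg/L had 1466 genes, and the cause was not tested. With an estimated correlation camera called 0 and 0 lists in A2780 at 20 and 40 mg/L (7 and 10 at an unadjusted p under 0.05, 18 and 21 by fry), 7 and 6 in SKOV3, and 1 and 5 between the lines, since that correlation widens the spread of a list.

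With each library left out in turn, and so fewer samples, the count between the doses in A2780 ran from 1583 (without 20 mg/L replicate 3) to 3499, with 1797 without 40 mg/L replicate 2. In SKOV3 at 20 mg/L it ran from 1443 (without DMSO replicate 3) to 1741. The other counts stayed within 1.5 times: 6587 to 6931 and 6458 to 6927 in A2780 at 20 and 40 mg/L, 10360 to 11197 in SKOV3 at 40 mg/L, 9259 to 10192 between the doses in SKOV3, and 4485 to 4901 and 6390 to 6895 between the lines.

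With the replicate number as a block the counts were 7255, 7312 and 2693 in A2780, 2537, 11622 and 10638 in SKOV3, and 5024 and 7031 between the lines. Oxidative phosphorylation then passed in SKOV3 at 40 mg/L (adjusted p = 0.0409). Between the doses in A2780 mitotic genes and fibroblast and endothelial markers lost their calls (0.0512 each). The TFRC difference between the lines at 20 mg/L passed (0.0482). The numbers do not pair the samples: correlations of libraries with the same number were -0.14 to 0.04 in A2780 and -0.08 to 0.10 in SKOV3.

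Of 3040 values for named genes, 3000 kept their direction and side of the threshold, 27 fell below it and 13 passed it. Of 3004 values for lists, 2752 kept both, 178 lost the call, 113 of them with an estimated correlation, and 74 gained it. No direction reversed beyond the threshold in any of these. Depth limits genes at a few counts, such as CD14, whose calls rested on single libraries.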

Other observations

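All tests in this part were chosen after the result was seen. Genes spanning over 300 kb had lower medians than genes of 10 to 30 kb in A2780 and SKOV3. In A2780 at 20 mg/L the median was -0.49 for the 288 genes of 300 to 500 kb (69.4% called lower) and -0.55 for the 164 genes above that (61.6%), among them DLG2 (log2 -1.80), against 0.05 for 10 to 30 kb. With 40 mg/L these medians were -0.23 (42.4%), -0.48 (53%) and 0. In SKOV3 at 40 mg/L they were -0.4 (62.9%), -0.66 (72.3%) and 0.07, and at 20 mg/L they were close to each other, at 0 (9.7%), -0.02 (9.7%) and 0.01.

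Exonic length or abundance is argued against as the whole cause. Against genes under 30 kb matched on both, long genes lay lower by a median of -0.65 in A2780 at 20 mg/L, -0.33 at 40 mg/L and -0.63 in SKOV3 at 40 mg/L (SE 0.04 each), and by only -0.06 (SE 0.01) in SKOV3 at 20 mg/L. They lay higher by 0.35 (SE 0.02) at 40 than at 20 mg/L in A2780. RNA breakdown would lower genes with long exonic sequence. At equal span and CPM it is argued against by slopes on exonic length of 0.0667 (SE 0.00345), 0.037 (SE 0.00364) and 0.0361 (SE 0.00476). Where span varies, it stays open. All SEs here treat genes as independent and measure no spread between libraries. Without the A2780 libraries of lowest mitochondrial share the differences of medians were -0.53 and -0.25 (-0.51 and -0.24 with them). No biological explanation was tested.

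In SKOV3 at 40 mg/L MT-RNR2 rose from 8360 ± 499 to 20200 ± 496 CPM (log2 1.27, SE 0.06, adjusted p = 5.19e-19), in 3 of 3 libraries above all DMSO libraries, while 12 of 13 mitochondrial mRNAs fell and MT-CO1 rose. More mitochondrial RNA as a whole is argued against by their median of -0.76, and reads moved from nuclear copies by a gain of 25 CPM in those copies against 11800 CPM in MT-RNR2. More RNA without a poly(A) tail stays open: 6 small or ribosomal nuclear RNAs rose by a median of 1.58, from 0.25 for RPPH1 to 2.91 for SNORD3A, but MALAT1, which also lacks that tail, had -0.01 and histone mRNAs a median of -0.42. No biological explanation was tested.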
